A study of Homo sapiens with 41 samples.

How the data were processed

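Transcript levels were measured by bulk RNA sequencing in 41 libraries: 18 of Hodgkin and Reed-Sternberg (HRS) cells and 17 of B cells, sorted by flow cytometry from tumour biopsies, and 6 of 4 cultured lines of classical Hodgkin lymphoma (cHL). Per the labels' protocols, RNA was isolated with a PicoPure kit and cDNA was made with a SMARTer kit for ultra-low input. The same protocols name a KAPA kit for library preparation and RPMI medium with serum for the lines. The submitters' processing notes name STAR 2.3.0e, HTSeq, limma and the genome build GRCh37, without saying which step each tool served. The annotation and the strand setting were not given. The deposited values were raw integer read counts per gene, 1 column per library, in a table of 27115 gene symbols, per the authors' table. Of the counts from 1 to 50, 64.1% were even, and 23658 values of 2 stood against 11057 values of 1, an excess that arises where the 2 reads of a fragment are counted apart; how the reads were counted was not given. Counting intervals and floors given with the values cover counting error only. They take the counts as deposited, so that they are too narrow where a fragment entered as 2.

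Groups were taken from the labels. 17 patients had both an HRS and a B library, matched by the patient numbers in the labels. As a check, the deviations of both libraries of a patient from their group means were correlated across genes, with a median r of 0.31 for own pairs and -0.147 for other pairs. Within groups and library sets (described in the report) the median r of own pairs was 0.105, against -0.0044 for other pairs. The patient number was not a term of the main test and served as a replicate block in an alternative. The 2 libraries of KMH2 and the 2 libraries of L428 were summed, since the unit of replication was the line, which left 4 lines. No libraries repeated another of the same group: the smallest chi-square per gene between libraries of 1 group was 98.3, in the B cells.

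Left out before any test were 115 symbols, those found only on the Y chromosome together with XIST and TSIX. Another 27 symbols had been turned into calendar dates, and these genes stayed in the totals and tests without being named. Of the 27000 genes kept, 2272 had no count in any library. No coordinates are given, because the counts rest on GRCh37 and the annotation at hand on another build. Matches of named genes to overlapping genes used that other annotation by symbol.

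Differential expression was tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group (minimum count 10, minimum total count 15), TMM factors, a robust quasi-likelihood fit and a two-sided quasi-likelihood F-test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. A second count took calls with at least a 2-fold change. The comparisons were HRS against B, lines against HRS and lines against B. Levels are given as log2 counts per M (CPM) with TMM factors and a prior count of 2, or as mean CPM. Where all libraries of a group were at 0, the fold was computed against a floor of 3 counts over the group and given as a bound. With 1 to 3 counts in a group, the ratio of pooled shares is given with its 95% counting interval.

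Of 31 gene lists fixed by textbook knowledge, 29 had members in the table and were tested with camera of limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation, and fry on voom values, served as alternatives. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The lists of immunoglobulin constant genes and of mitochondrial genes had no member in the table and were not tested. CD24, IGHD, IGHM, TRAC, TRBC1 and TRBC2 were absent from it. Members called are counted over all genes and, where stated, adjusted over the list alone. The themes of natural killer (NK) cell ligands and of the unfolded protein response (UPR) were taken from the study's title, which rests on the same libraries, so that these lists are not independent evidence of their direction.

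Groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. For HRS against B, the rule took called genes that differed in the same direction in all 17 pairs with a mean of at least 10 CPM in the higher group, the 10 largest changes upward and the 10 largest downward. For each comparison with the lines it took the 8 largest changes each way among called genes with that level and all 4 lines on one side of the other group's median. Rearranged V, D and J segments, Y-linked genes, XIST, TSIX and unnamed genes were excluded. The rule also took the 4 members of each list with the smallest adjusted p, and any member of the lists on NK ligands, both MHC classes, both UPR branches, Hodgkin markers and B-cell identity. Other genes are marked where they appear as chosen after their values were seen.

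Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom without and with quality weights, no filter on low counts, a stricter filter, the replicate block, the patient as a random effect, only patients with both libraries, removal of immunoglobulin and mitochondrial genes, all 6 line libraries as if independent, and each line left out in turn. Alternatives added after the data were seen were the library set as a term, each library set alone, the first line libraries against set 2, halved counts, and the tests without 3 libraries that stood apart. Those 3 were chosen for a low number of detected genes, a high mean of T-cell markers, and a high TNFRSF8 level in the B group. In tests on simulated data with 50 changed genes at each fold, edgeR found 46% of 4-fold changes for HRS against B, 4% for lines against HRS and 26% for lines against B. At 8-fold it found 76%, 36% and 52%. It called 2, 0 and 1 of the unchanged genes in these comparisons, where DESeq2 called 18, 173 and 97.

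Library totals ran from 16.1 to 89.0 M counts in HRS, from 25.9 to 75.7 M in B and from 33.7 to 41.5 M in the line libraries.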

Results

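Transcript levels were measured by bulk RNA sequencing in 41 libraries from Hodgkin lymphoma. HRS cells, the malignant cells of classical Hodgkin lymphoma, gave 18 libraries, and B cells sorted from the same kind of biopsy gave 17. Both came from flow sorting, and 17 patients had both kinds of library. Another 6 libraries came from 4 established cHL lines: KMH2 and L428 with 2 libraries each, and HDLM2 and L1236 with 1 each. Total counts per library, in M (mega), had a median of 48.3 M in HRS (16.1 to 89.0), 41.9 M in B (25.9 to 75.7) and 37.1 M in the line libraries (33.7 to 41.5). The median number of genes with at least 1 count was 15664 in HRS, 15857 in B and 17009 in the line libraries.

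Within HRS and within B, the libraries fell into 2 sets that the labels did not name. The first component of log2 CPM centred on each group held 26.0% of the variance, and the gap between the sets spanned 32.0% of its range. Set 1 held 9 HRS and 8 B libraries with a median of 62.2 M counts, and set 2 held 9 HRS and 9 B libraries with a median of 32.7 M. Both libraries of each of the 17 patients fell in the same set. The sets were drawn from these same values, so that many calls between them were built in and are no separate support for the sets. Both libraries of a patient also entered that test as separate units. Of 14706 genes tested, 3884 were higher and 4234 lower in set 1 with group as a term. Among these were histone genes, which encode the core of chromatin, with 22 of 63 higher and 1 lower in set 1, and small RNA genes, with 34 of 320 higher and 136 lower. Both of these classes were chosen after their values were seen. The plot of set differences by GC content shows the difference in both cell types and between repeat libraries of 2 lines. For HRS against B, values within each set are given for the main lists and for named genes whose call ended in 1 of the sets.

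**Figure D1:**
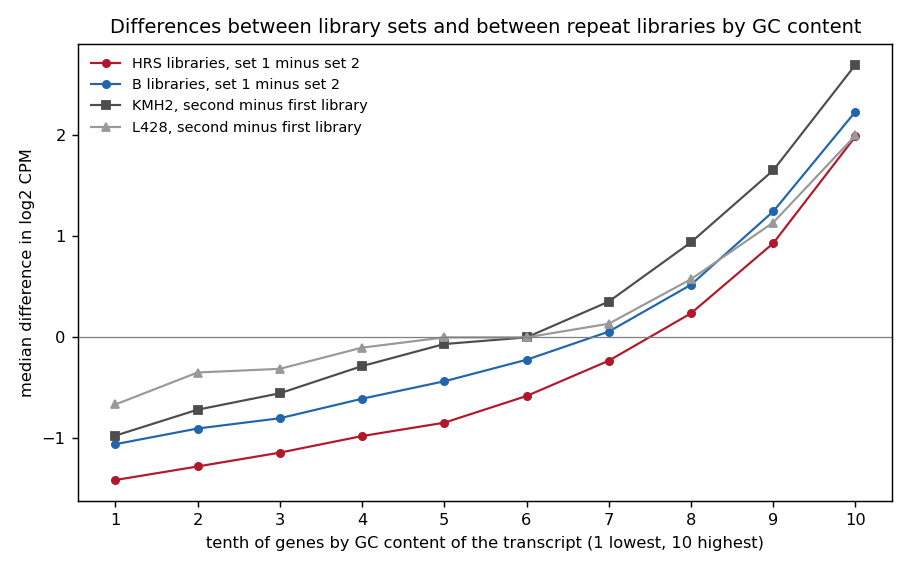
Median difference in log2 CPM (vertical axis) by decile of genes ranked by GC content of the transcript (horizontal axis, 1 lowest, 10 highest), for set 1 minus set 2 in HRS and in B libraries and for the second minus the first library of KMH2 and of L428. In HRS the median went from -1.41 in the lowest decile to 1.99 in the highest, and in B from -1.06 to 2.24.

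HRS cells were compared with intratumoral B cells because the study asked how the malignant cells differ from the non-malignant cells of the lineage they derive from. HRS cells carried far more transcript of TNFRSF8, the receptor CD30 that marks them in diagnosis, with a mean of 266 CPM in HRS (n = 18) and 3.34 CPM in B (n = 17), a log2 fold change of 6.37 ± 1.01 (SE). CCL17, a chemokine that attracts T-helper cells, rose by 6.25 ± 0.97. MS4A1, the B-cell surface antigen CD20, had a log2 fold change of -6.56 ± 0.87. TNFRSF8 and CCL17 were higher, and MS4A1 lower, in the HRS library of all 17 pairs (edgeR adjusted p = 2.8e-06, 2.0e-06 and 1.4e-07). Much of the TNFRSF8 and CCL17 level in B came from 1 library: without it the B mean of TNFRSF8 was 0.533 CPM and that of CCL17 fell from 201 to 31.4 CPM (16 libraries left). This library was picked for its TNFRSF8 level, so that a larger change of TNFRSF8 without it was built in. Without the 3 libraries that stood apart, this one among them, TNFRSF8 was at 9.10 and CCL17 at 9.08, and with patients as a replicate block they were at 9.87 and 8.96. They were at 5.78 and 5.68 within library set 1, and at 8.98 and 9.15 within set 2.

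Of 14706 genes tested, 3649 were higher and 3040 lower in HRS cells, 6689 in all or 45.5%. A change of at least 2-fold was called for 3006 upward and 2587 downward. With patients as a replicate block, 7869 genes were called, 3652 higher and 4217 lower, as the median log2 fold change of all genes moved from 0.02 to -0.19. Limma-voom called 2978 higher and 4438 lower, so that which direction held more genes depended on the setting. That median was -0.32 in limma-voom, -0.22 with its quality weights, 0.28 without the filter on low counts, 0.12 with the stricter filter and 0.11 without the 3 libraries that stood apart. Within library set 1 there were 5064 calls and within set 2 there were 6326, and 3671 genes were called in both, 3670 of them in the same direction. Across 13152 genes tested in both sets, the fold changes had r = 0.89, where genes are not independent replicates. Without the 3 libraries that stood apart, increases were larger for CCL22 (8.46), IL13 (8.92), BATF3 (8.00), THEMIS (8.33), PDCD1LG2 (5.78), SLC7A11 (6.71), ID2 (6.82) and WNT5A (9.00), as were the decreases of STAP1 (-7.94) and CD79B (-7.47), while NECTIN2 was no longer called (1.71, adjusted p = 0.103).

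The largest increases among genes that differed the same way in all pairs included 3 genes of signalling proteins. CSF2, the growth factor GM-CSF, had a mean of 179 CPM in HRS and 0.327 CPM in B, and a log2 fold change of 9.14 ± 1.18. PDGFRA, a receptor tyrosine kinase for platelet-derived growth factor, had 185 and 0.401 CPM and a change of 8.88 ± 0.98. It is also on the list of stromal and endothelial markers, of which 5 of 8 were higher and 1 lower. WNT5A, a secreted WNT ligand, had 137 and 0.416 CPM and a change of 8.39 ± 0.94. The other 7 were the cadherin CDH8 (10.31 ± 1.23), ENOX1 (10.20 ± 0.85), SNAR-C3 (9.69 ± 1.31), EML1 (9.58 ± 0.80), FLJ41278 (9.56 ± 1.02), CPNE4 (9.40 ± 0.95) and the vesicle protein CADPS (8.46 ± 1.22), with adjusted p of at most 5.6e-07. Reads of SNAR-C3, 1 of a family of near-identical copies, of ENOX1, which overlaps ENOX1-AS2 on the opposite strand, and of CPNE4, which overlaps MIR5704, were not separable from those genes here.

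The largest decreases included FCRL2, an Fc receptor-like protein of B cells, with 0.618 CPM in HRS and 251 CPM in B and a log2 fold change of -8.73 ± 0.85. CD180, a Toll-like receptor homologue of B cells, had 0.475 and 191 CPM and a change of -8.71 ± 0.81. TCL1B (-8.77 ± 1.02), the cannabinoid receptor CNR2 (-8.04 ± 0.84) and the lipid-presenting CD1A (-8.10 ± 0.96) fell as well. The other 5 were the non-coding RNAs LINC01013 (-10.06 ± 0.80), LINC01800, LOC105369723, LINC01781 and MIR5195, which lies in an immunoglobulin locus. Each of the 10 was lower in the HRS library of all 17 pairs, which the rule for naming them required. CDH8 and TCL1B were not tested within library set 2, for low counts.

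**Figure D2:**
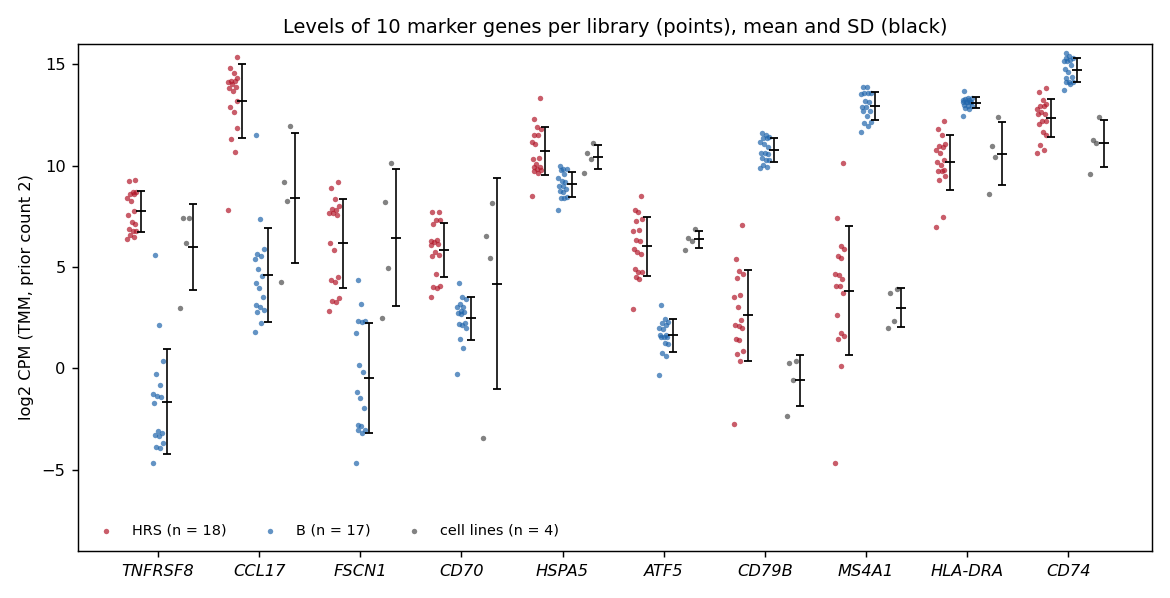
Levels (log2 CPM, vertical axis) of 10 marker genes (horizontal axis) in each library of HRS (n = 18), B (n = 17) and cell lines (n = 4, libraries summed per line); points are libraries and black marks with bars are the mean and SD. TNFRSF8 had a mean of 266 CPM in HRS and 3.34 CPM in B, or 0.533 CPM in B without the library highest in it.

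Genes of the Hodgkin phenotype rose together. Of 35 tested Hodgkin markers, 25 were higher and 4 lower (27 and 4 adjusted over the list alone), with a median log2 fold change of 4.41 (camera adjusted p = 2.7e-14). CD80 and CD86, ligands that costimulate T cells, rose by 4.64 ± 0.33 and 3.98 ± 0.31. CCL22, a chemokine for regulatory T cells, rose by 7.06 ± 0.75, and GATA3, a transcription factor of T-helper cells, by 5.22 ± 0.59. ID2, an inhibitor of the B-cell factor TCF3, rose by 5.92 ± 0.53. The 4 lower members were STAT6, the activation marker CD83, the receptor NOTCH1 and RYK, with changes of -0.92, -1.33, -1.93 and -0.86. Within library set 2, NOTCH1 and RYK were not called, at -1.20 and -0.53 (adjusted p = 0.0552 and 0.132). T-cell markers rose in the same libraries, 19 of 23 with a median of 4.42. The mean of all T-cell markers that passed the filter, called or not, was above that of the highest B library in 9 of the 18 HRS libraries. Without the 3 libraries that stood apart, 26 Hodgkin markers were higher and 4 lower, and 17 T-cell markers were higher and 1 lower.

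B-cell genes fell. Of 32 B-cell identity genes, 29 were lower in HRS cells and 3 did not pass the test, with a median log2 fold change of -4.52 (camera adjusted p = 7.1e-21), and of -6.17 with the replicate block and -6.85 in limma-voom. CD79B, a signalling chain of the B-cell receptor, fell by 6.64 ± 0.66 on the log2 scale and the tetraspanin CD37 by 2.84 ± 0.26. PAX5, the factor that commits cells to the B lineage, fell by 2.14 ± 0.45 (adjusted p = 1.6e-04). The factors EBF1, SPIB and TCF3 had changes of -1.03 ± 0.81, 0.31 ± 0.45 and 0.20 ± 0.40 (adjusted p = 0.310, 0.600 and 0.715). EBF1 was called with the replicate block (-3.60, adjusted p = 0.0031), within library set 1 (-4.27, adjusted p = 0.0047) and in limma-voom (-4.91). Among genes of naive and memory B cells, 16 of 19 fell and 1 rose, with a median of -4.82 (camera adjusted p = 1.1e-09), and with the replicate block 18 fell, with a median of -7.37 (-7.41 in limma-voom). TCL1A, a coactivator of the kinase AKT, fell by 7.47 ± 0.78, whereas the lymph node homing receptor CCR7 rose by 2.99 ± 0.26. Among germinal centre genes, 9 of 16 fell, among them LMO2 (-6.85) and STAP1 (-6.71), with a median of -2.94 (camera adjusted p = 1.4e-04, and adjusted p = 0.0595 with an estimated correlation). Plasma-cell genes went both ways, with 7 of 15 higher and 5 lower, a median of 0.56 and a mean of -0.10 (camera adjusted p = 0.691), and with the replicate block 6 were higher and 7 lower, with a median of -0.25. SEC11C, a subunit of the signal peptidase, rose by 2.70 ± 0.24, and TNFRSF17, the survival receptor BCMA, fell by 6.40 ± 0.92.

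Genes of MHC class II presentation fell in HRS cells, and those of class I were not called as a list. Of 18 genes of MHC class II presentation, which shows peptides to CD4 T cells, 16 were lower and 1 higher, with a median log2 fold change of -2.18 (camera adjusted p = 3.5e-14). HLA-DMB, which helps load peptides, fell by 3.86 ± 0.27, HLA-DRA by 2.51 ± 0.30, and CIITA, the transactivator of these genes, by 3.11 ± 0.37, each in all 17 pairs. The higher member was RFXANK, a factor that binds class II promoters (0.91 ± 0.26). Of 19 genes of MHC class I presentation, 10 were lower and 1 higher (10 and 2 adjusted over the list alone), with a median of -0.78 and no call for the list (camera adjusted p = 0.127). HLA-E, the ligand of the NK receptor NKG2A, fell by 2.67 ± 0.35, and NLRC5, the transactivator of class I genes, by 1.88 ± 0.26. HLA-B and HLA-C, classical class I chains, fell by 1.81 ± 0.45 and 1.57 ± 0.46, and B2M, their shared light chain, by 1.72 ± 0.35. PSME2, a proteasome activator subunit, rose by 1.30 ± 0.22. With the replicate block the class I list was called (adjusted p = 0.0445). Within library set 1, B2M was at -0.65 (adjusted p = 0.214).

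The question of how HRS cells meet NK cells was addressed with 18 tested genes of ligands for activating NK receptors. Of these, 8 were higher and 3 lower in HRS cells (8 and 4 adjusted over the list alone), with a median log2 fold change of 1.39 and no call for the list (camera adjusted p = 0.368). CD70, the ligand of CD27, rose by 3.69 ± 0.43, ICAM1, an adhesion ligand of LFA-1, by 2.88 ± 0.36, and CD58, the ligand of CD2, by 1.42 ± 0.27. PCNA, a replication clamp that can also engage NKp44, rose by 3.15 ± 0.20, and it is on the list of proliferation genes too. PVR, a ligand of DNAM-1, rose by 7.17 ± 1.45 and was higher in HRS in 12 of 17 pairs. It passed the filter on low counts neither with the replicate block, nor without the 3 libraries that stood apart, nor within library set 1, and within set 2 it was at 5.07 (adjusted p = 0.0011). SLAMF6, a receptor that binds itself on NK cells, fell by 5.30 ± 0.85, CD48, the ligand of 2B4, by 3.08 ± 0.68 and CLEC2B, the ligand of NKp80, was at -3.84 ± 0.73. MICA and MICB, stress ligands of NKG2D, were at -1.20 ± 0.61 and -0.52 ± 0.52 (adjusted p = 0.107 and 0.438). With the replicate block 5 of 17 NK ligands were higher and 6 lower (median 1.12). The increases of NECTIN2 (3.34 ± 1.06) and ULBP2 (2.90 ± 0.97) were then no longer called, at 1.99 (adjusted p = 0.211) and 3.51 (adjusted p = 0.0605). MICA was then at -2.37 (adjusted p = 0.0253), SLAMF7 at -3.13 (adjusted p = 0.0214) and BAG6 at -0.63 (adjusted p = 0.0336), each newly called. Within library set 1, CLEC2B was at -3.03 (adjusted p = 0.0649), NECTIN2 at 3.31 (0.0887) and ULBP2 at 3.51 (0.0664), none called. In set 2 ULBP2 was not called either (2.65, adjusted p = 0.0801), and NECTIN2 was not tested there, nor ULBP3 in set 1, for low counts. Among genes of resistance to death receptors and NK effectors, 3 of 9 were higher and 3 lower (median 0.23, camera adjusted p = 0.397), with CFLAR, an inhibitor of caspase 8, up by 2.50 ± 0.20.

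Genes of the unfolded protein response, which adjusts the folding capacity of the endoplasmic reticulum, were tested as 2 branches, of which the targets of IRE1 and ATF6 rose also with an estimated correlation and the targets of PERK and ATF4 with the preset one alone (adjusted p = 0.196 with an estimated correlation). Of 37 targets of IRE1 and ATF6, 21 were higher and 3 lower, with a median log2 fold change of 1.11 (camera adjusted p = 1.7e-05). HSPA5, the master chaperone BiP, had a mean of 2351 CPM in HRS and 586 CPM in B and rose by 2.09 ± 0.34 (adjusted p = 5.5e-06, higher in 16 of 17 pairs). The chaperones HSP90B1 and HYOU1 rose by 2.19 ± 0.18 and 2.66 ± 0.25, the disulfide isomerase PDIA6 by 2.05 ± 0.20, and XBP1, the factor that IRE1 activates by splicing, by 1.92 ± 0.40. The 3 lower members serve protein disposal: the ubiquitin ligase SYVN1 (-2.49 ± 0.30), its cochaperone partner DNAJB9 (-1.11 ± 0.43) and the mannosidase-like EDEM2 (-0.78 ± 0.19). HERPUD1 and ATF6 were at 0.08 ± 0.30 and -0.01 ± 0.35 (adjusted p = 0.852 and 0.985). Within library set 1, DNAJB9 was not called, at -0.87 (adjusted p = 0.382).

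Of 26 targets of PERK and ATF4, 17 were higher and 2 lower (18 and 2 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 9.4e-04, and adjusted p = 0.196 with an estimated correlation). ATF5, a factor of the mitochondrial and amino acid stress response, rose by 4.83 ± 0.43, the serine synthesis enzyme PSAT1 by 4.27 ± 0.55 and the cystine transporter SLC7A11 by 5.73 ± 1.05. ATF4 itself rose by 0.54 ± 0.19 (adjusted p = 0.0201). The 2 lower members were DDIT3, the proapoptotic factor CHOP (-1.01 ± 0.30), and EIF2AK3, the kinase PERK itself (-1.86 ± 0.32). CHAC1, which degrades glutathione, was at 2.39 ± 0.99 (adjusted p = 0.0462) and, with the replicate block, at 0.71 (adjusted p = 0.638). It was not called in either library set alone, and within set 1 ATF4 and DDIT3 were at 0.37 and -0.72 (adjusted p = 0.149 and 0.103).

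**Figure D3:**
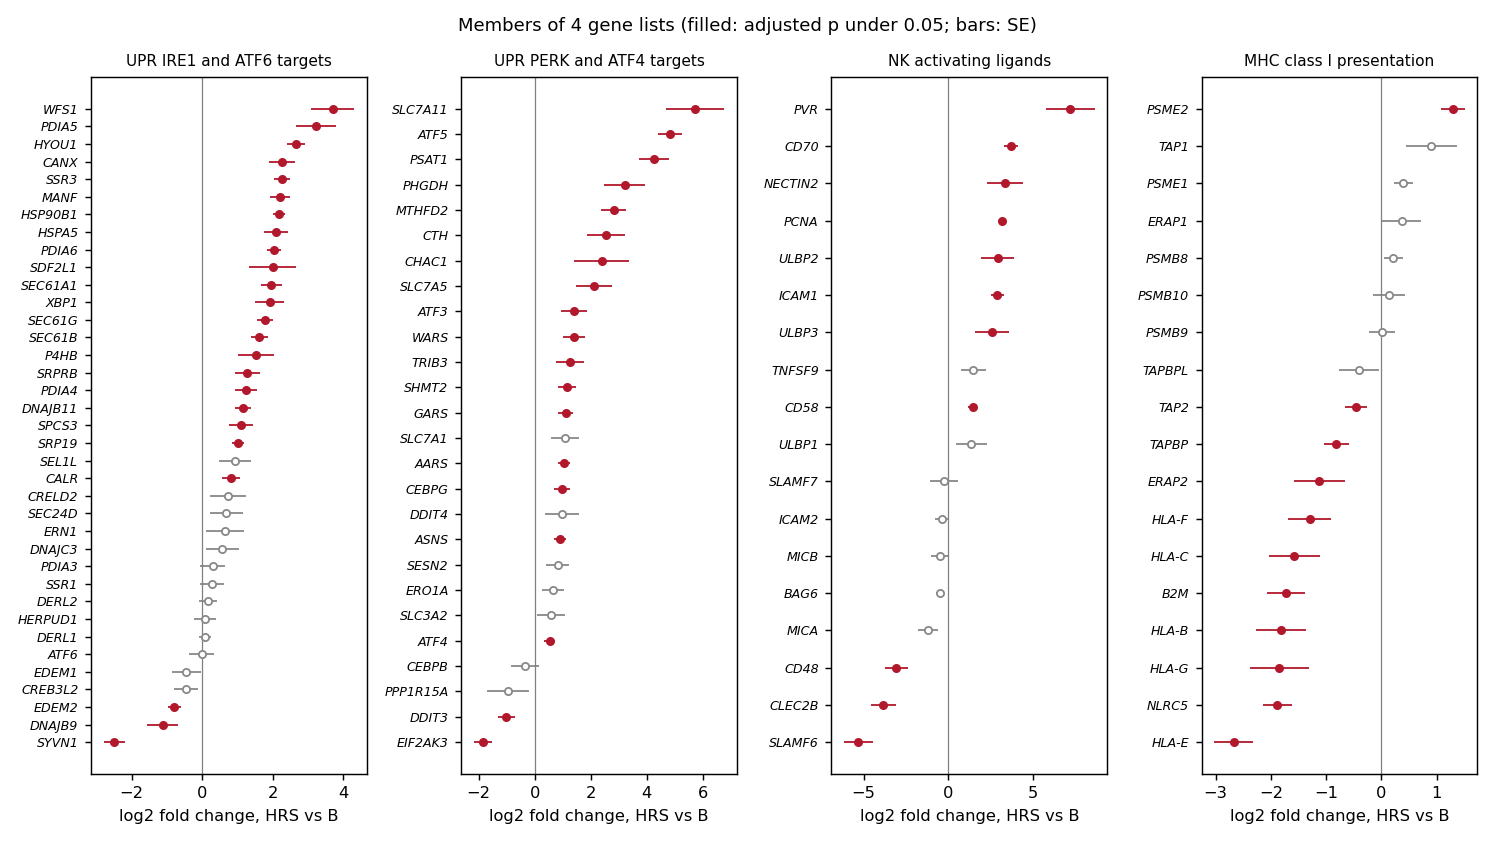
Log2 fold change of HRS (n = 18) against B (n = 17) on the horizontal axis for the tested members, named on the vertical axis, of 4 lists (targets of IRE1 and ATF6, targets of PERK and ATF4, NK ligands, MHC class I presentation); bars are SE and filled points have an adjusted p under 0.05, and 1 member of the class I list that was not called is not drawn. The lists had 21, 17, 8 and 1 members called higher and 3, 2, 3 and 10 called lower.

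Growth genes were among the most uniform. Of 30 proliferation genes, 29 were higher, with a median log2 fold change of 4.19 (camera adjusted p = 3.9e-32): CCNB1, the cyclin that drives entry into mitosis, rose by 3.97 ± 0.28, and the kinetochore protein CENPF by 4.51. Of 20 glycolysis genes, 12 were higher and 1 lower, with a median of 0.91 (camera adjusted p = 8.0e-05, and adjusted p = 0.0613 with an estimated correlation). PKM and LDHA, which make pyruvate and lactate, rose by 2.61 ± 0.16 and 2.13 ± 0.21. Among apoptosis regulators 9 of 23 were higher and 6 lower (median 0.40, camera adjusted p = 0.274). BCL2L1, the survival protein BCL-XL, rose by 3.54 ± 0.31, the death receptor FAS by 3.49 ± 0.31, and the initiator caspase CASP8 fell by 1.55 ± 0.27. Targets of NF-kB, a pathway active in HRS cells, rose as a list, with 13 of 31 higher and 6 lower (15 and 7 adjusted over the list alone) and a median of 0.64 (camera adjusted p = 6.9e-04, and adjusted p = 0.206 with an estimated correlation). TRAF1, a signalling adaptor, rose by 4.73 ± 0.44, and IER3, an early response gene, by 5.16 ± 0.48.

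The remaining signalling lists held members of both directions. Chemokines and cytokines had 12 of 25 higher and 6 lower (13 and 6 adjusted over the list alone) and a median of 1.35. This list was not called (camera adjusted p = 0.0637) and was called with the replicate block (adjusted p = 0.0400). IL13, a cytokine of T-helper cells and a growth factor of HRS cells, rose by 7.33 ± 0.96 and LTA by 4.06 ± 0.48, in libraries where T-cell markers rose by a median of 4.42. Immune checkpoint ligands had 9 of 21 higher and 6 lower (10 and 6 adjusted over the list alone; median 1.27, camera adjusted p = 0.0861). With the replicate block 7 of 20 were higher and 8 lower, and the median was 0.18. CD274, the ligand PD-L1, rose by 6.21 ± 0.64, in 16 of 17 pairs, and PDCD1LG2, the ligand PD-L2, by 4.67 ± 0.76. Within library set 1 PDCD1LG2 was not called, at 2.92 (adjusted p = 0.0802), and within set 2 the list of checkpoint ligands was called (adjusted p = 0.0301). JAK-STAT genes had 7 of 27 higher and 8 lower, with a median of -0.15, a mean of 0.29 and a test that pointed down (camera adjusted p = 0.648). STAT5A rose by 2.22 ± 0.28, its target CISH by 5.17 ± 0.63, and the phosphatase PTPN6 fell by 3.36 ± 0.41. AP-1 factors had 4 of 13 higher and 4 lower, with a median of -0.41, a mean of 0.36 and a test that pointed up (camera adjusted p = 0.910). BATF3, an AP-1 factor of HRS cells, rose by 6.23 ± 0.77, and FOSB fell by 2.84 ± 0.49. Interferon response genes fell as a list, with 17 of 30 lower and 3 higher and a median of -1.51 (camera adjusted p = 9.9e-04, and adjusted p = 0.357 with an estimated correlation). XAF1, an antagonist of caspase inhibitors, fell by 3.29 ± 0.55, and the antiviral enzyme OAS1 by 1.52.

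Markers of other cell types that a lymph node biopsy holds also differed. T-cell markers rose with a median log2 fold change of 4.42 (camera adjusted p = 9.9e-04, and adjusted p = 0.399 with an estimated correlation). CD3D, a chain of the T-cell receptor complex, was at 4.88 ± 0.81, the coreceptor CD4 at 4.61 ± 0.86, and THEMIS, a signalling protein of developing T cells, at 6.45 ± 0.92. Within library set 1 the list's median was 3.88 with no call (camera adjusted p = 0.0557), and within set 2 it was 4.94 (adjusted p = 1.6e-04). Stromal markers had 5 of 8 higher, PDGFRA among them, and 1 lower (6 and 1 adjusted over the list alone, median 3.95, camera adjusted p = 0.142). They were called with the replicate block (median 5.57, adjusted p = 0.0140). With the replicate block 13 of 23 T-cell markers were higher and 1 lower (median 3.39, adjusted p = 0.0112). NK-cell markers had 4 of 10 higher and 2 lower, with a median of 2.17, a mean of 0.91 and a test that pointed down (camera adjusted p = 0.911), and with the block 1 of 7 was higher and 1 lower (median 0.97). Macrophage markers had 2 of 14 higher (median 0.42, camera adjusted p = 0.901), one of which, AIF1, was at 3.09 ± 0.84 without the block and at -0.25 with it (adjusted p = 0.789), and at 0.73 in library set 1 (adjusted p = 0.608) against 4.25 in set 2 (0.0043). Granulocyte markers had 2 of 3 higher (median 3.56, camera adjusted p = 0.297) and dendritic-cell markers 2 of 6 higher and 4 lower (median -2.72, camera adjusted p = 0.109). With the block 1 of 3 granulocyte markers was higher (median 4.21), and 1 of 6 dendritic-cell markers was higher and 4 lower (median -5.78). Of 5 erythroid markers, edgeR called 0 and DESeq2 and limma-voom called 0 as well, with 0 at an unadjusted p under 0.05 in edgeR (median -0.24, camera adjusted p = 0.911 pointing up). Genes of the dissociation and stress response had 11 of 21 lower and 3 higher (median -1.58, camera adjusted p = 0.109). With the block this list was called, with 15 lower and 3 higher (adjusted p = 0.0140), as it was within library set 2 (adjusted p = 0.0294). Ribosomal protein genes had 5 of 45 higher and 6 lower (4 and 4 adjusted over the list alone), with a median of -0.10 and a test that pointed up (camera adjusted p = 0.911). These genes had 8 higher and 1 lower within library set 1 (median 0.40), within set 2 they had 3 higher and 8 lower (median -0.14), and with the block 10 higher and 8 lower (median 0.10).

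Of the 29 lists, 12 were called for HRS against B, and 6 of these calls held with an estimated correlation: Hodgkin markers, B-cell identity, proliferation, MHC class II presentation, naive and memory B-cell genes, and targets of IRE1 and ATF6. With the replicate block MHC class I presentation, chemokines, stromal markers and stress genes were added, and no list lost its call. Within each library set alone the 12 lists were called, except T-cell markers in set 1. In sets 1 and 2 the medians were 3.76 and 4.81 for Hodgkin markers, -5.30 and -4.14 for B-cell identity, -2.42 and -1.90 for MHC class II, 1.21 and 1.11 for targets of IRE1 and ATF6, 1.03 and 1.15 for targets of PERK and ATF4, and 3.78 and 4.63 for proliferation. They were -0.68 and -0.36 for MHC class I, 0.25 and 1.31 for NK ligands, and 1.22 and 1.45 for chemokines and cytokines, which were called in neither set.

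**Figure D4:**
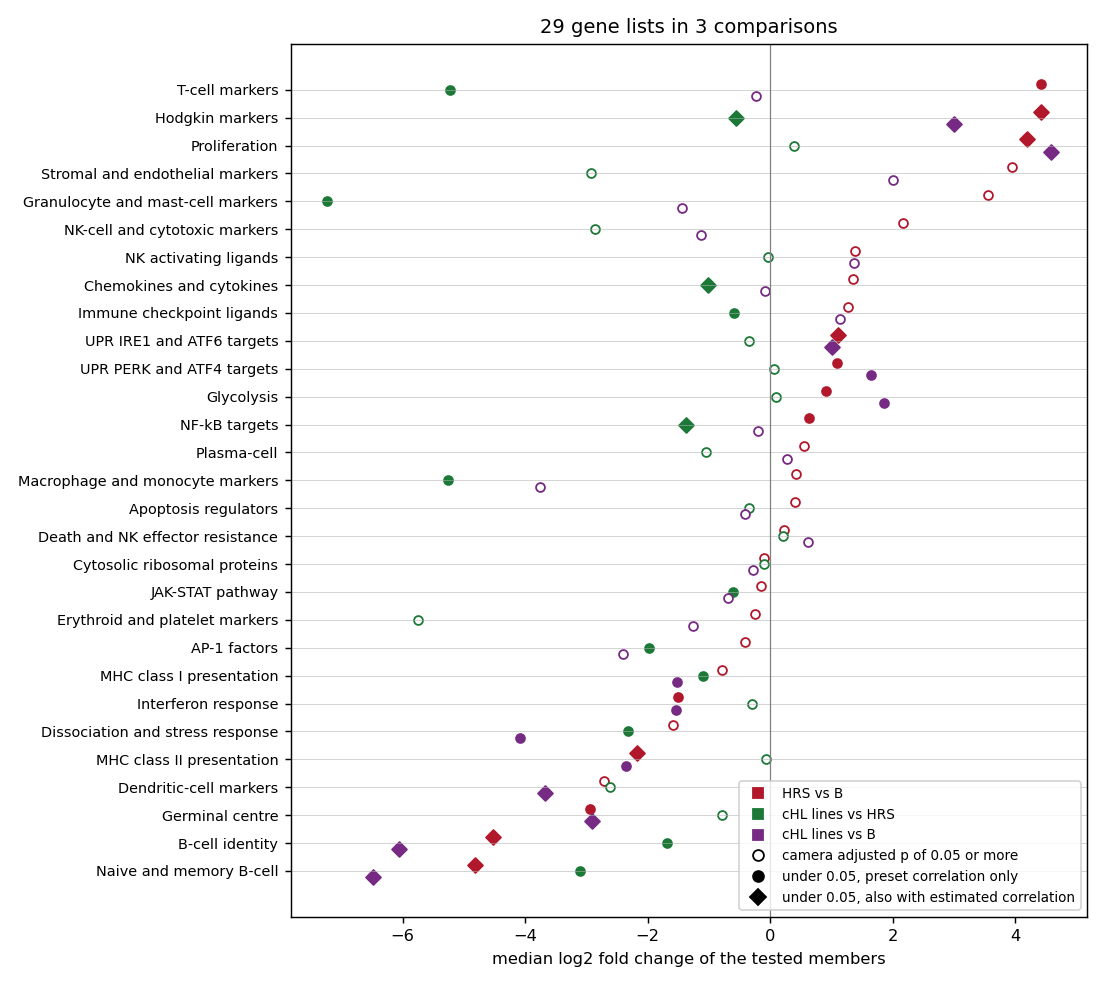
Median log2 fold change of tested members (horizontal axis) of 29 gene lists (vertical axis) for HRS against B, lines against HRS and lines against B; open points have a camera adjusted p of 0.05 or more, filled circles one under 0.05 with the preset correlation alone, and filled diamonds one under 0.05 also with an estimated correlation. Of the 29 lists, 12, 13 and 13 were called in these comparisons.

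The 4 lines were compared with sorted HRS cells to see where the cultured models of the disease differ from the malignant cells of biopsies. GPR15, a chemoattractant receptor of lymphocytes, had a mean of 103 CPM in the lines (n = 4) and 0.0192 CPM in HRS (n = 18), a log2 fold change of 12.25 ± 1.11 (adjusted p = 8.4e-07). BCHE, the enzyme butyrylcholinesterase, was higher in the lines by 8.84 ± 1.56, and SSX1, a cancer-testis gene, by 11.40 ± 1.49. SIGLEC10, an inhibitory lectin of B cells and macrophages, fell by 6.60 ± 1.03, and FOS and FOSB, immediate early AP-1 factors, had changes of -8.08 ± 1.57 and -6.56 ± 1.26. All 4 lines lay on the same side of the HRS median for each of these 6 genes, which the rule for naming them required. SSX1 was uneven among the lines, with a mean log2 CPM of 0.44 (SD 4.76, n = 4), and had 10 counts in all HRS libraries together.

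Of 17794 genes tested, edgeR called 34 higher and 13 lower in the lines, 47 in all, each by at least 2-fold. The number of lower calls depended on the lines: 3 were called without HDLM2 (44 higher) and 4 without L1236 (33 higher), against 10 without KMH2 and 9 without L428. DESeq2 called 959, of which 158 were higher, and limma-voom called 290, of which 252 were higher. The median log2 fold change of all genes was -0.13, and it was 0.31 in limma-voom. Fold changes of the lines followed GC content and transcript length, with a Spearman rho across genes of -0.236 and 0.240 against HRS and of -0.155 and 0.155 against B, where HRS against B had 0.020 and -0.060. Whether this trend came from library preparation or from the cells was not tested. GPR15, LOC105372582 (6.42 ± 1.09) and SIGLEC10 were called with any 1 line left out, as was BCHE, but SIGLEC10 was not called in limma-voom (adjusted p = 0.0787) nor BCHE in DESeq2 (adjusted p = 0.119) or with the first line libraries against set 2 (adjusted p = 0.0583). The remaining named genes each lost their call without at least 1 line. Without HDLM2, the call of PMCH (6.61 ± 1.42), which overlaps PARPBP on the opposite strand, ended at 0.66 (adjusted p = 0.927). Without L428, LRRN3 (7.73 ± 1.45), which overlaps IMMP2L on the opposite strand, was at 3.46 (adjusted p = 0.521), and without KMH2, MAGEA10 (8.08 ± 1.75), which overlaps LOC100533997, was at 0.93 (adjusted p = 0.917) and SSX1 at 4.73 (adjusted p = 0.254). FOS lost its call without HDLM2, L1236 or L428 (adjusted p = 0.0664 to 0.0760) and in limma-voom (0.308), and FOSB without HDLM2, KMH2 or L428 (0.0656 to 0.0761) and in limma-voom (0.143). The lines had a mean log2 CPM of 0.85 (SD 0.90) for FOS and of -0.63 (SD 0.98) for FOSB. IL27 (-9.30 ± 2.04) and TCEAL4 (-8.45 ± 1.76) lost theirs without HDLM2, L1236 or L428 (adjusted p = 0.0964 to 0.122 and 0.0766 to 0.104), IPCEF1 (-9.94 ± 2.03), which overlaps OPRM1 on the opposite strand, without HDLM2, KMH2 or L428 (0.0763 to 0.0834), and MECOM (6.41 ± 1.34) without KMH2 or L428 (0.116 and 0.0848). RNU4-2 (-7.46 ± 1.64), which overlaps SIRT4 on the opposite strand, and HIST1H4B (-7.08 ± 1.54) were not called without any 1 of the 4 lines (adjusted p = 0.109 to 0.131 and 0.0996 to 0.134). Reads of these overlapping genes were not separable here.

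Few single members of the lists were called in the lines against HRS, and 13 lists moved as sets, all downward. Targets of NF-kB had a median log2 fold change of -1.38 with 1 of 32 lower (9 adjusted over the list alone; camera adjusted p = 6.9e-12). Hodgkin markers had a median of -0.55 (camera adjusted p = 8.7e-06), with edgeR calling 0 of 35 members (1 higher and 7 lower adjusted over the list alone). At an unadjusted p under 0.05, 3 were higher and 11 lower, and DESeq2 called 7 lower and limma-voom 1 higher and 2 lower. TNFRSF8 was at -1.43 ± 0.67 (adjusted p = 0.369) and CCL22 at -7.30 ± 1.63 (adjusted p = 0.0508). Chemokines and cytokines had a median of -1.02 (camera adjusted p = 7.0e-05), with 1 of 30 lower (1 higher and 7 lower adjusted over the list alone). These 3 lists were called with an estimated correlation too (adjusted p = 0.0139, 0.0139 and 0.0354), and the other 10 were not.

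Markers of other cells, stress genes and presentation genes were also lower in the lines than in HRS as lists. T-cell markers had a median of -5.23 (camera adjusted p = 1.4e-10, and adjusted p = 0.105 with an estimated correlation), with edgeR calling 0 of 24 members (10 lower adjusted over the list alone), 14 lower at an unadjusted p under 0.05, DESeq2 13 and limma-voom 1. Stress genes had a median of -2.32 with 2 of 21 lower, 10 adjusted over the list alone (camera adjusted p = 5.5e-11, and adjusted p = 0.0720 with an estimated correlation). MHC class I genes had a median of -1.10 (camera adjusted p = 2.7e-07, and adjusted p = 0.0720 with an estimated correlation), with edgeR calling 0 of 19 members (10 lower adjusted over the list alone), 10 lower at an unadjusted p under 0.05, DESeq2 5 and limma-voom 0. B-cell identity had a median of -1.69 (camera adjusted p = 2.7e-05, and adjusted p = 0.105 with an estimated correlation), with edgeR calling 0 of 32 members, 11 lower at an unadjusted p under 0.05, DESeq2 6 and limma-voom 0. The medians of AP-1 factors (-1.99), JAK-STAT genes (-0.61), macrophage markers (-5.27), naive and memory B-cell genes (-3.11), checkpoint ligands (-0.59) and granulocyte markers (-7.23) were also called lower. With an estimated correlation, these 6 lists had an adjusted p = 0.0893, 0.0959, 0.105, 0.184, 0.105 and 0.140. Checkpoint ligands were not called without L1236 (camera adjusted p = 0.0828).

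The themes of the study's title and MHC class II were not called in the lines against HRS with all libraries. Targets of IRE1 and ATF6 had a median of -0.34 (camera adjusted p = 0.0865, and 0.0465, called lower, without the libraries that stood apart), and targets of PERK and ATF4 a median of 0.06 and a mean of -0.24 (camera adjusted p = 0.915). NK ligands had a median of -0.03 and a mean of 0.07 (camera adjusted p = 0.696), and MHC class II genes a median of -0.07 (camera adjusted p = 0.226, and 0.0027 without HDLM2). In these 4 lists edgeR called 0 members (2 NK ligands higher adjusted over the list alone). At an unadjusted p under 0.05 it gave 2 higher and 9 lower, 3 and 2, 2 and 1, and 0 and 2, in that order. DESeq2 called 2, 2, 1 and 0 members and limma-voom 0, 1, 0 and 0. Proliferation genes, at a median of 0.39 (camera adjusted p = 0.0672), were called with the first line libraries against HRS libraries of set 2 alone (adjusted p = 1.6e-05), without HDLM2 (0.0017) and without KMH2 (0.0386). Glycolysis genes (median 0.10, camera adjusted p = 0.279) were called in the same set 2 comparison (adjusted p = 0.0015).

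The lines were compared with the B cells to see which differences of HRS cells the models carry against the same reference. CD79B, a chain of the B-cell receptor, fell by 11.14 ± 0.76 on the log2 scale, and BANK1, a B-cell scaffold protein, by 9.85 ± 0.56. TNFRSF8 rose by 5.02 ± 1.38, and by 7.57 with the first line libraries against set 2 and 8.20 in limma-voom. It rose by 7.70 without the B library that stood apart, which was picked for its TNFRSF8 level. CD274 rose by 5.78 ± 0.70, and by 2.92 without HDLM2. HYOU1, a chaperone of the endoplasmic reticulum, rose by 3.75 ± 0.27. All 4 lines lay on the same side of the B median for each of these genes (adjusted p = 3.1e-10, 2.7e-11, 0.0057, 8.4e-07 and 5.4e-10). CCL17, which was higher in HRS, was at 2.61 ± 1.33 (adjusted p = 0.123) and, without that B library, at 5.35 (adjusted p = 1.6e-05). It was at 0.66 without HDLM2 (adjusted p = 0.780) and was called in limma-voom (3.74, adjusted p = 0.0086) and with the first line libraries against set 2 (6.20, adjusted p = 3.6e-05).

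Of 16736 genes tested, 3930 were higher and 2817 lower in the lines, 6747 in all or 40.3%, of which 3606 and 2696 changed by at least 2-fold. With upper-quartile factors the median log2 fold change of all genes moved from 0.04 to -0.17, and 3285 genes were called higher and 3220 lower. DESeq2 called 3562 higher and 3829 lower. The largest increases by the rule were led by BCHE, which had no counts in B and was at least 7558-fold higher, with NDST4 (12.88 ± 1.45), an enzyme of heparan sulfate synthesis, COL22A1 (11.90 ± 0.92), CD109 (11.54 ± 0.96), the homeobox gene HOXB9 (11.48 ± 0.94) and ONECUT2 (11.31 ± 0.98). NDST4 was uneven among the lines, with a mean of 319 CPM but a mean log2 CPM of 3.28 (SD 6.57, n = 4). B4GALNT1, a ganglioside synthase with 1 count in B, had a ratio of 13630 (95% counting interval 2446 to 538352), and SLC26A10, with 2 counts, a ratio of 5920 (1639 to 48883). These 2 genes overlap, and their reads were not separable here. Genes with no counts in the lines were at least 4314-fold (P2RX1, an ATP-gated channel), 2538-fold (MIR650, in an immunoglobulin locus), 2348-fold (ZNF439), 2074-fold (ST14), 1542-fold (LDOC1) and 1466-fold lower (DNASE1L3, a secreted nuclease). TBC1D10C had a change of -13.20 ± 2.38, and LOC105369723, with 1 count in the lines, a ratio of 15406 (2765 to 608492).

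By list, 13 of 29 were called in the lines against B. B-cell identity genes fell in 28 of 32 (30 adjusted over the list alone; median -6.06, camera adjusted p = 7.8e-36), and naive and memory B-cell genes in 16 of 19 with 1 higher (18 and 1 adjusted over the list alone; median -6.49, adjusted p = 5.0e-18). Proliferation genes rose in 29 of 30 (median 4.59, camera adjusted p = 8.1e-24) and Hodgkin markers in 24 of 35 with 1 lower (24 and 3 adjusted over the list alone; median 3.00, adjusted p = 1.5e-05). Targets of IRE1 and ATF6 rose in 15 of 37 and fell in 4 (16 and 4 adjusted over the list alone; median 1.01, adjusted p = 0.0015). HSPA5 was at 1.42 ± 0.32 and HSP90B1 at 1.78 ± 0.21, both called. These 5 lists, germinal centre genes (median -2.91) and dendritic-cell markers (median -3.68) held with an estimated correlation. Targets of PERK and ATF4 rose in 14 of 27 and fell in 2 (median 1.65, camera adjusted p = 9.0e-04, and adjusted p = 0.107 with an estimated correlation), with PSAT1 at 5.85 ± 0.67 and ATF5 at 4.69 ± 0.36.

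Antigen presentation genes fell in the lines against B, as sets with the preset correlation alone. MHC class II genes fell in 14 of 18 (median -2.36, camera adjusted p = 4.7e-09, and adjusted p = 0.0802 with an estimated correlation), among them HLA-DMB (-3.76 ± 0.36). MHC class I genes fell in 12 of 19 (median -1.52, camera adjusted p = 7.6e-04, and adjusted p = 0.153 with an estimated correlation). HLA-E was at -4.67 ± 0.64 and was called. B2M was at -1.56 ± 0.48 and lost its call without L428 (adjusted p = 0.0526). Glycolysis genes rose in 13 of 20 with 1 lower (median 1.85, camera adjusted p = 6.4e-06, and adjusted p = 0.0814 with an estimated correlation). Stress genes fell in 14 of 21 with 2 higher (median -4.08, camera adjusted p = 7.1e-05, and adjusted p = 0.299 with an estimated correlation). Interferon response genes fell in 11 of 30 (median -1.55, camera adjusted p = 4.1e-04, and adjusted p = 0.426 with an estimated correlation). NK ligands had 9 of 19 higher and 5 lower (10 and 5 adjusted over the list alone) and no call for the list (median 1.37, camera adjusted p = 0.522). PVR was at 6.35 ± 1.28, ULBP1, a ligand of NKG2D, at 5.42 ± 1.12, SLAMF6 at -5.19 ± 1.12 and CD48 at -2.98 ± 0.80, each called. T-cell markers had 6 of 22 higher and 6 lower (median -0.23, camera adjusted p = 0.203). Medians of lists with members at 0 counts in a group, such as dendritic-cell markers, were the same with those members at their bound.

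The overlap of HRS against B with lines against B was counted because both use the same B libraries. Of 14649 genes tested in both, 6632 and 6118 were called, 2425 higher in both and 1809 lower in both, 4234 in all, and 47 in opposite directions. Independent calls at these numbers would share 864 higher and 538 lower. The fold changes had r = 0.77 across genes and a covariance of 4.33. In unchanged groups simulated with shared controls, r was 0.285 and the covariance 0.103. EdgeR called 0 genes in each simulated comparison, so that 0 shared calls followed and do not bear on the shared count. All simulated groups had the means and spread of the B libraries, without the library sets. With the B libraries split into separate controls for each comparison, the median of 20 draws was a covariance of 4.76 with 2919.5 shared calls. With any 1 line left out, 3796 to 3881 calls were shared. TNFRSF8, CD274, HSPA5 and PSAT1 were among the genes higher in both, and CD79B, HLA-DRA and SLAMF6 among those lower in both.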

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

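The tests of T-cell carry-over for the markers and for THEMIS, the test of the handling of biopsy cells, and the alternatives with library sets, halved counts or without libraries that stood apart were chosen only after the results were seen.

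In 4 of 56 results tested, the gap between 1 of the 4 lines and the nearest other line exceeded the 95% critical value of Dixon's test for 4 samples. Chance alone gives about 1 in 20 such groups, so that these 4 carry little weight as a pattern. PMCH was at 6.37 log2 CPM in HDLM2, with the nearest line at -1.17 and the farthest at -1.69. IL27 was at -1.88 log2 CPM in KMH2, IPCEF1 at -1.46 in L1236 and LOC105369723 at -4.26 in L428, each with the other 3 lines at no counts (-4.67). With 3 lines at the floor the gap makes up the whole range whatever the remaining line holds, so that these 3 values say little, and LOC105369723 had 1 count in all lines together.

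The number of genes called was compared with that of other splits of the libraries into groups of the same sizes. Each comparison had 100 splits with the real one included, so that no rank below 1 of 100 was possible. Most other splits mix the groups in each arm, which raises the spread. Their counts therefore do not measure the size of the difference. For HRS against B the real split called 6689 genes and the highest other split 3. Among these 100 splits the real one alone reached its count, and the same held in each comparison. Among 100 splits that part every pair, the highest other called 1822. A split that follows the library sets, which was not among the 100, called 6954 genes, more than the real one. Those sets were drawn from the first component of the same values. A high count was therefore built in and cannot be weighed against that of the real split. Within set 1 the real split called 5064 genes and within set 2 6326. For lines against HRS the real split called 47 genes and the highest other 12, and for lines against B 6747 and 909.

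T-cell markers were higher in HRS than in B libraries, 19 of 23 called. A difference between library sets is argued against by the medians within the sets, 3.88 and 4.94, and a single library by 17 of 19 markers that stayed called without the HRS library richest in them. For THEMIS, carried-over T cells are argued against as the whole source by 8 of 9 HRS libraries that held no more of the other called markers than the highest B library and yet had more THEMIS than any B library. For the other markers T cells carried over in the sort, or bound to HRS cells, remain a candidate source consistent with the test: 16 of 19 markers had an r of at least 0.5 with the mean of the others across HRS libraries, against at most 4 in 1000 shuffles, with CD3D at a mean of 4.90 and CD3E at 3.53 log2 CPM in HRS (0.54 and 0.16 in B). The sort by flow cytometry was meant to remove such cells, and expression by HRS cells stays open too: 6 of the 19 markers were also called higher in the lines than in B, although CD2 and CD247 only with HDLM2 (-2.63 and -2.88 without it) and CD4, BCL11B and UBASH3A only with KMH2 (0.77, 3.36 and 2.94 without it), and in limma-voom only THEMIS, BCL11B and UBASH3A.

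HRS and B libraries fell into 2 sets with 26.0% of the variance on 1 component. Differences between patients as the whole cause are argued against by repeat libraries of a line, which differed along the same genes with r = 0.384 in L428 and 0.497 in KMH2 across 17985 genes. Depth is argued against by thinning, after which the component held 27.2% of the variance and 35 of 35 libraries kept their side. GC content bias may account for a part, with a Spearman rho across genes of 0.515 in HRS and 0.579 in B between GC content and the set difference. Gene length bias (rho -0.275 in HRS and -0.224 in B) cannot be told apart from GC content here, since each was tested without holding the other fixed. A change of library chemistry or date stays open because the labels name none.

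Stress genes were lower in the lines than in HRS libraries, with a median of -2.32. The first line libraries against HRS libraries of set 2 gave a median of -1.46 and a camera adjusted p of 8.6e-07. This argues against the mix of 2 sets among the HRS libraries as the whole source. Whether the line libraries resemble either set was not tested, so that a difference in library preparation stays open. Handling of the biopsy cells during dissociation and sorting could raise such genes in both sorted cell types, and 14 of 21 members were lower in the lines than in B too. It cannot be told apart from growth in culture, because all lines were cultured and all sorted cells came from biopsies. A difference between the cells in the body and in culture, which the design names, stays open as untested.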

How the results depend on the processing

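The alternatives with library sets, halved counts or without libraries that stood apart were chosen after the data were seen; the others were planned. Called genes for HRS against B ranged from 5064 to 10990, for lines against B from 5729 to 8991, and for lines against HRS from 29 to 959. Without the low-count filter, which tests more genes, HRS against B gave 10990 (9936 at least 2-fold) and lines against HRS 539 (539), including all 47. For lines against HRS, DESeq2 gave 959 (946 at least 2-fold), limma-voom 290 (290), its quality weights 460 (457), the 6 libraries as if independent 466 (466) and the stricter filter, which tests fewer genes, 29 (29). They shared 37, 34, 37, 42 and 29 genes with the 47, and on simulated data DESeq2 called 173 unchanged genes in this comparison, so that its count is too high by an unknown share. The cause of the limma-voom counts was not tested; repeat libraries taken as independent understate the spread. Leaving out 1 line gave 37 to 47 genes for lines against HRS (3 to 10 of them lower, against 13) and 5891 to 6163 for lines against B.

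Called lists fell with an estimated correlation to 6 for HRS against B, 3 for lines against HRS and 7 for lines against B. Fry, which does not compare lists with other genes, called 21 for HRS against B and 1 for lines against HRS. MHC class I presentation for HRS against B was called with the replicate block (adjusted p = 0.0445) and by fry (6.0e-04), and targets of PERK and ATF4 lost their call with an estimated correlation (0.196); the cause was not tested. AIF1 for HRS against B turned to -0.0058 in limma-voom and -0.25 with the replicate block. With the block, 14 named genes gained and 8 lost a call, AIF1 among the latter, 210 kept their call and 37 had none with or without it, and for lists it changed no call beyond the 4 it added. For lines against B, 3 genes turned with the first line libraries against set 2: BAG6 (-0.37), DDIT4 (1.58) and SLC3A2 (1.17). With 1 line left out, values ran from -0.067 (without KMH2) to 2.66 for CSF1R, from -0.97 (without HDLM2) to 5.57 for IL2RA, from -6.66 (without L428) to 2.97 for PHGDH and from -0.39 (without HDLM2) to 7.41 for PRF1. With halved counts, HRS against B gave 6493 calls of 13922 genes tested, against 6689 of 14706. In simulated data 4-fold changes were found in 46%, 4% and 26% of genes in the 3 comparisons, which set 18 against 17, 4 against 18 and 4 against 17 units.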

Other observations

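Both gene groups below were put together after the comparisons had been seen, and the genes named here were chosen after their values were seen, while the tests of the groups were set before they were run.

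Receptor tyrosine kinases, growth factor receptors that are silent in most B cells, were among the genes higher in HRS cells outside the fixed lists. Of 41 on a list of the family, without those on the fixed lists or named in the report, 19 were tested for HRS against B, with 9 higher and 1 lower and a median log2 fold change of 2.14. The list as a whole was not called (camera adjusted p = 0.194, 0.228 with an estimated correlation). Members silent in B were tested only where HRS libraries hold them. MERTK, a receptor for the clearance of dead cells, was at 7.36 ± 1.33 (higher in 13 of 17 pairs) and MET, the receptor of hepatocyte growth factor, at 6.07 ± 1.01 (17 of 17). The lower member was EPHB6, at -2.30 ± 0.62. In the lines against HRS the family had a median of -0.20 (camera adjusted p = 0.812), and in the lines against B 6 of 24 were higher and 4 lower (camera adjusted p = 0.517).

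Cancer-testis genes are silent in most adult tissues outside the germ line. Of 62 on the list, 6 were tested for HRS against B, and 4 of these were higher in HRS, with a median of 4.17. A gene silent in B passes the filter on low counts only where HRS libraries hold it. These counts and the median therefore do not show a trend of the whole group. PRAME had a mean of 444 CPM in HRS and 6.14 CPM in B, at 6.18 ± 1.04, and MAGEB1 and MAGEB2 were at 7.13 ± 1.41 and 6.33 ± 1.38. The list as a whole was not called there (camera adjusted p = 0.10, 0.202 with an estimated correlation) nor in the lines against B, with 6 of 9 higher and 1 lower (adjusted p = 0.0615, 0.120 with an estimated correlation). The filter limits the counts in the lines against B in the same way.

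As hypotheses, receptor tyrosine kinases may be broadly higher in HRS than in B cells, and cancer-testis genes broadly higher in the lines than in HRS cells. Neither was settled. For the first, camera gave an adjusted p of 0.194 (0.228 with an estimated correlation). The bound set beforehand took a missed p as exclusion, which was wrong, since a missed p excludes nothing and 9 of 19 members rose. For the second, the 18 tested members, which leave out SSX1 and MAGEA10, had a camera adjusted p of 0.805 and a median of -0.40. That median met the bound of at most 0 set beforehand, but by less than its standard error of 0.797, with members on both sides, so that it does not exclude the hypothesis either.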
